A study of Homo sapiens with 10 samples.

How the data were processed

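Gene expression was measured in total RNA from 2 established human leukaemia lines, BV173 and HL-60, cultured for 72 hours either alone or together with mesenchymal stromal cells derived from umbilical cord. BV173 is a line from a B-lymphoid blast crisis of chronic myeloid leukaemia, and HL-60 is an acute promyelocytic or myeloblastic leukaemia line. There were 10 one-colour arrays (Agilent SurePrint G3, Cy3 label), 1 per sample: 3 for BV173 alone, 3 for BV173 in co-culture, 2 for HL-60 alone and 2 for HL-60 in co-culture. The submitters describe the BV173 samples as independent biological replicates. For HL-60 nothing in the sources used here says whether the samples came from separate cultures, so the spread between them may be technical. P-values for HL-60 rest on a spread pooled over all 10 arrays, mostly those labelled BV173, and not on the HL-60 samples alone. How the leukaemia cells were separated from the stromal cells before RNA extraction is not given in the sources used here. Groups were taken from the sample source labels, and replicate numbers only name the arrays.

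The deposited scanner files give spot intensity on a linear scale. Per the file headers and the submitters' processing notes they were made with Agilent Feature Extraction 10.7.1.1, whose processed signal is already corrected for local background and is not normalized between arrays. The authors also deposited 1 normalized table per line, with values on a log2 scale. Their scale, centring and direction are not stated, so they were set against the scanner values. Differences between groups in these tables followed the log2 differences of the scanner values, with a correlation across genes of 1.00 for BV173 and 0.999 for HL-60. The column medians lay between -0.0245 and 0.19, and the baseline that each probe was centred on stayed unknown. Of the 4 columns of the table for HL-60, 2 matched the scanner values of each other's array within the same group, which leaves group means as they are. These tables were used only as an alternative, each tested within itself.

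Each array held 58717 spots that are not controls, for 50599 probes. Between 54.3% and 59.8% of the spots were well above background on each array, and no spot was saturated. The number of arrays limits the precision. Spots of 1 probe were averaged, and the processed signal was taken as log2 minus the array's 75th percentile of the signal over non-control probes. All levels below are on this log2 scale. Probes with an outlier flag on an array (88) and probes of 114 sex-linked features were left out. Probes were named through their unversioned RefSeq accession in a table of assembly GRCh38.p14 genes, used for names only: 28174 probes matched 1 gene each, giving 20503 genes, and 22425 had no name. A probe was tested if it was well above background on all arrays of at least 1 group. A gene was represented by its probe with the highest mean over the 10 arrays, and unnamed probes stood for themselves. This left 23980 features, called genes below, of which 15685 had a symbol.

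Replicate numbers follow only the order of the records and were not used to pair arrays. Each HL-60 group had 1 array on each slide, so the HL-60 comparison was also made within each slide and with slide as a block. Tests were made with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, in a single fit of all 10 arrays with 4 groups, which leaves 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method and called at an adjusted p below 0.05. The comparisons were co-culture against alone in each line, the difference between these 2 effects, and BV173 alone against HL-60 alone as a check of the labels. A gene that was not well above background on any array of a group has only a bound there. The bright group's mean was then set against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal, and the result is written as "at least N-fold". Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 33 lists fixed before the data were examined, with an estimated correlation and with fry beside it. Of the 831 list entries 820 were on the array. On simulated arrays with 23980 genes, the BV173 comparison recovered 31 of 50 genes changed by 1 log2 unit and 47 of 50 changed by 2. The HL-60 comparison recovered 26 of 50 and 41 of 50. Of 50 genes changed by 0.5 log2 units the BV173 comparison recovered 3 and the HL-60 comparison 0. Few genes were changed in these simulations and their noise was independent, so recovery on the real arrays may differ.

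The genes named in the text follow a rule fixed before the data were examined. It takes the 8 largest rises and the 8 largest falls per comparison among genes with a symbol that passed the test, were well above background on all arrays of both groups and had no overlap between the groups' arrays. It adds up to 4 genes per direction with only a bound in 1 group, the 4 members with the largest change of each list that passed or is described, the 5 largest differences between the lines in each direction, and the 5 genes with the largest shared and the 5 with the largest opposite change. Clone, LOC and non-coding identifiers were not named. CD47, CD274, CXCR4, CD44, BCR, ABL1, MYC, BCL2 and CDKN1A could be given whatever their result. Some genes under this rule and 1 of the lists are left out of the text. Other genes named in the text were chosen after their values were seen, and are marked so.

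The arrays lay on 2 slides, each scanned together. Slide 1 held all BV173 arrays and 1 array of each HL-60 group, and slide 2 held 1 array of each HL-60 group. The alternatives tried were quantile normalization, a percentile over probes above background on all arrays, normexp background correction with an offset of 50, no filter and a stricter filter on dim probes, other rules for the probes of a gene, separate fits per line, slide as a block, slide 1 only, a variance trend with robust estimation, the authors' tables, stricter thresholds, leaving out each array and, for the difference between the lines, the sign of the BV173 comparison turned. Replicates of 1 group correlated between 0.989 and 0.994 across genes, none were identical, and all arrays were kept. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.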

Results

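Expression was profiled on 10 arrays after 72 hours of culture. The series asks how mesenchymal stromal cells from umbilical cord change the transcriptome of leukaemia lines. It holds 3 arrays labelled BV173 alone, 3 labelled BV173 in co-culture, 2 labelled HL-60 alone and 2 labelled HL-60 in co-culture. Between 54.3% and 59.8% of spots were well above background on each array.

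The labels were checked first with lineage genes of both lines in the arrays labelled alone. Genes of B-cell precursors were far higher on the arrays labelled BV173, where 21 of 22 passed the limma test and the list's median difference was 6.89 log2 units, or 6.35 with genes at their bounds, as 11 of the 22 were well above background on no array labelled HL-60 alone (camera adjusted p = 3.7e-14; adjusted p = 0.0301 with an estimated correlation). The pre-B receptor gene VPREB1 lay at 7.49 on the arrays labelled BV173 alone, and DNTT, which encodes the terminal transferase of lymphoid precursors, lay at 6.61, and neither was well above background on those labelled HL-60. Promyelocyte granule genes did not set the lines apart in the way the labels would place them. Of the 16 listed, 10 were tested. LYZ was not on the array, and the rest were in no group well above background on all arrays, HL-60 groups included. Of the 10 tested, 2 were higher on the arrays labelled HL-60 and 4 were higher on those labelled BV173, and the list did not pass (adjusted p = 0.269; adjusted p = 0.701 with an estimated correlation). Among genes well above background on all arrays it did pass (adjusted p = 0.0119), with 0 genes higher on the arrays labelled HL-60, and over the other alternatives its adjusted p lay between 0.107 and 0.385. MPO, the myeloperoxidase of these granules, lay at -3.63 on the arrays labelled HL-60 alone and -0.33 on those labelled BV173 alone. Erythroid and megakaryocyte genes were higher on the arrays labelled HL-60 alone for 11 of 13 genes and lower for 2, with a median difference, BV173 minus HL-60, of -4.63, or -4.28 with bounds (adjusted p = 9.78e-05; adjusted p = 0.173 with an estimated correlation). Among them HBG1, a fetal globin, lay at 9.90 against -0.71, and GATA1, the erythroid transcription factor, at 4.50, where it was not well above background on the arrays labelled BV173. The text therefore speaks of arrays labelled HL-60.

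**Figure D1:**
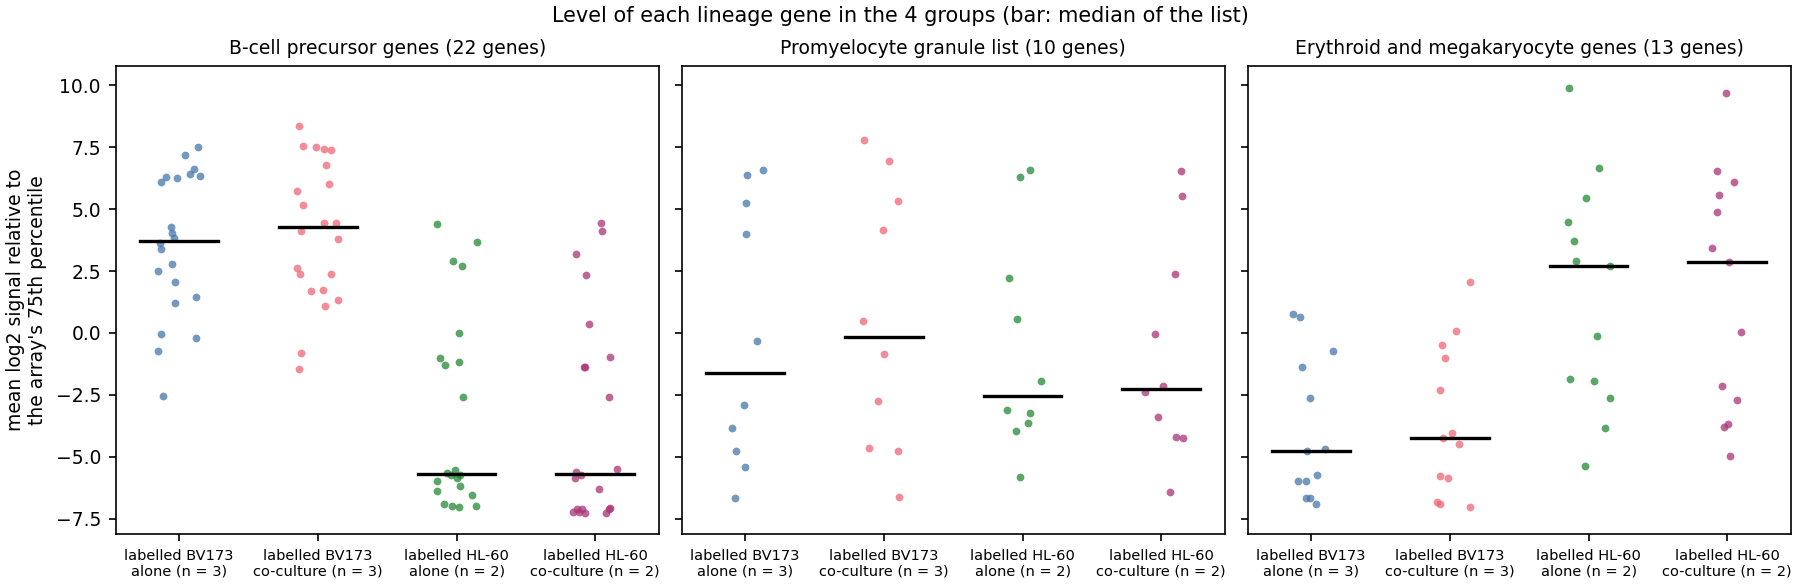
Mean log2 level, relative to the array's 75th percentile, of each gene of 3 lineage lists in the 4 groups. Each point is a gene, bars are list medians and n is the number of arrays; B-cell precursor genes have medians of 3.73 and 4.27 on the arrays labelled BV173, and erythroid genes have medians of 2.70 and 2.85 on those labelled HL-60.

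The first comparison asks what co-culture changed in BV173. Stromal genes went against the labels: they were high on the arrays labelled BV173 alone and low on the arrays labelled BV173 in co-culture. All 36 stromal genes were well above background on all 3 arrays labelled alone, and 19 of them were above it on no array labelled co-culture. The list median was 3.08 on the former and -5.48 on the latter. Of the 36 genes, 34 were lower and 2 were higher on the arrays labelled co-culture (the 2 were COL6A3 and S100A16, named after their values were seen), with a median log2 fold change of -8.08, or -6.72 with genes at their bounds. The camera adjusted p was 2.48e-29, against an adjusted p = 0.199 with an estimated correlation. CCN1, a matricellular protein, was at least 6110-fold lower on the arrays labelled co-culture. TGFBI, an extracellular matrix protein, was at least 5300-fold lower, THY1, the stromal surface antigen CD90, at least 1760-fold lower and COL1A2, a chain of type I collagen, at least 1130-fold lower. Every direction for BV173 below follows the labels and carries this conflict.

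**Figure D2:**
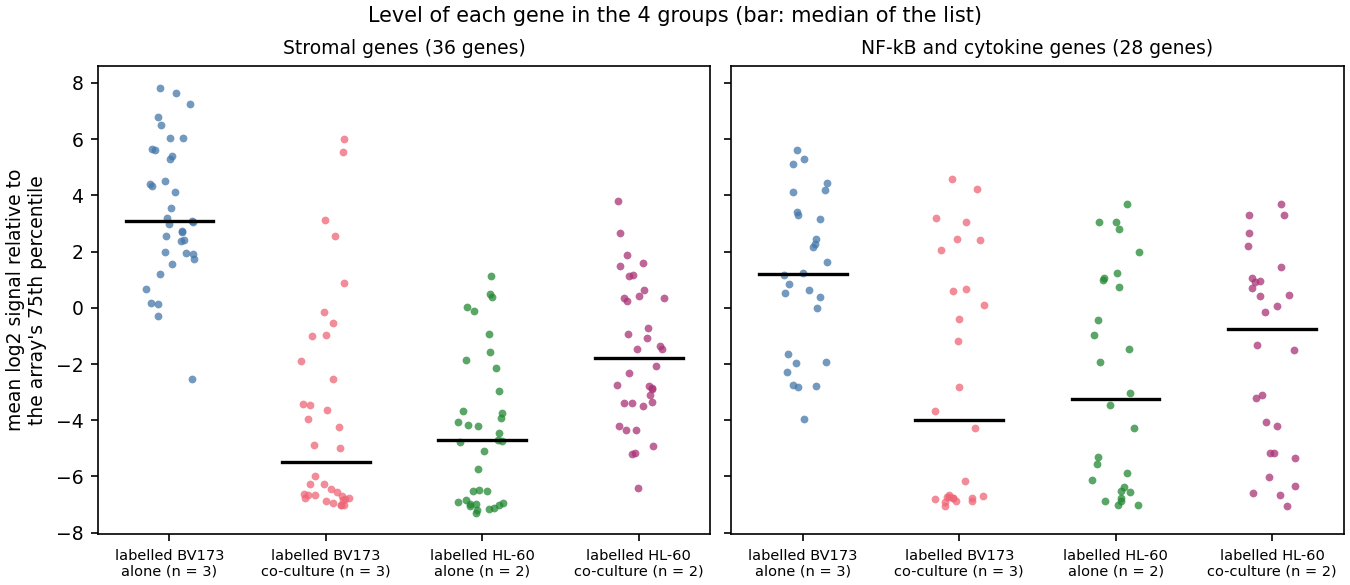
Mean log2 level, relative to the array's 75th percentile, of each stromal gene and of each NF-kB and cytokine gene in the 4 groups. Each point is a gene, bars are list medians and n is the number of arrays; the stromal medians are 3.08, -5.48, -4.72 and -1.78 from left to right.

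On the arrays labelled BV173 in co-culture 6289 of 23980 genes were higher and 3614 were lower than on those labelled alone, and 1155 and 2295 of these changed by at least 1 log2 unit. The median over all genes tested was 0.19, and it was -0.014 when the percentile was taken over probes above background on all arrays, where 42.8% of the calls were higher against 63.5%. Among genes well above background on all arrays 74.3% of the calls were higher. Among genes well above background on all arrays of both groups, the largest differences in the lower direction were in COL6A1, a collagen chain, with a log2 fold change of -10.46 (SE 0.22, n = 3 per group, limma adjusted p = 1.52e-08), and in ACTA2, smooth muscle actin, with -9.47. GREM1, a BMP antagonist, followed with -9.15, FSTL1 with -9.04, GDF15, a stress cytokine, with -8.52, KRT19 with -7.94, HTRA1 with -7.41 and LGALS3 with -6.99. UCHL1 was at least 3740-fold lower and S100A6 at least 3220-fold lower. In the higher direction SCIMP, an immune membrane adaptor, lay at -3.55 ± 0.20 on the arrays labelled alone and at 0.97 ± 0.17 on those labelled co-culture (SD, n = 3), a log2 fold change of 4.52. KCNMB3 differed by 3.66, LTB, which encodes lymphotoxin beta, by 3.51, PSG3 by 3.20, CTSG by 3.02, ROBO4 by 3.01, LGR5 by 2.99 and GIMAP8 by 2.97. The call of GIMAP8 (adjusted p = 0.0437) was lost without any 1 of the 6 arrays labelled BV173 and without the first array labelled HL-60 in co-culture (adjusted p from 0.0501 to 0.105), with the percentile over probes above background on all arrays (0.0756) and with no filter on dim probes (0.0858). HECW1 was at least 8.67-fold higher, PSG1 at least 8.08-fold, PSG6 at least 6.56-fold and THBS4 at least 6.37-fold. The PSG genes are near-identical paralogs, so their probes do not give independent values.

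Of the 33 gene lists, 13 passed for the arrays labelled BV173, 8 lower and 5 higher on those labelled co-culture, and 12 of these are described. With an estimated correlation camera called none of the 33, with 5 at an unadjusted p under 0.05, and fry, which asks only whether a list moves one way, called 22. For each list below the count adjusted over the list alone is given where it differs from the count over all genes. NF-kB targets, cytokines and chemokines were lower for 21 of 28 genes and higher for 2, and lower for 22 adjusted over the list alone. Their median log2 fold change was -3.34, or -1.97 with bounds (adjusted p = 2.27e-13; adjusted p = 0.199 with an estimated correlation). The neutrophil chemokine gene CXCL1 was at least 931-fold lower, with a log2 fold change of -5.51 at its other probe, the cytokine gene IL6 at least 581-fold, CCL2 at least 464-fold and CXCL8 at least 283-fold. TGF-beta and BMP targets were lower for 13 of 20 genes and higher for 2 (median -1.03, adjusted p = 4.6e-06; adjusted p = 0.199 with an estimated correlation). LTBP1, which binds latent TGF-beta, was at least 83.4-fold lower, with -5.33 at its other probe, and BAMBI, a pseudoreceptor, at least 30.5-fold. These groups moved with the stromal list, which differed by a median of -8.08 between the same arrays.

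Lysosome and autophagy genes were lower for 13 of 27 genes and higher for 5, and higher for 6 adjusted over the list alone (median -0.21, adjusted p = 0.000819; adjusted p = 0.531 with an estimated correlation), led by the protease CTSL at -5.33, WIPI1 at -5.29, GABARAPL1 at -4.40 and CTSB at -2.87. ATF4 response genes were lower for 10 of 31 genes and higher for 3 (median -0.065, adjusted p = 0.013; adjusted p = 0.818 with an estimated correlation). This call ended with each probe as a feature (adjusted p = 0.0575), in a range over the alternatives from 0.000103 to 0.818. NUPR1 was at least 284-fold lower, VLDLR at least 6.88-fold lower, and ASNS, asparagine synthetase, differed by -3.67. Oxidative stress genes were lower for 8 of 20 genes and higher for 2 (median -0.31, adjusted p = 0.0161; adjusted p = 0.704 with an estimated correlation), with HMOX1, haem oxygenase, at -6.11, SRXN1 at least 36.7-fold lower and the metallothionein MT1F at 1.81. Epithelial markers were lower for 4 of 8 genes (median -0.33, adjusted p = 0.0159; adjusted p = 0.199 with an estimated correlation), and these were the keratin genes KRT19, KRT18 at -3.30 and KRT8 at -1.003, with -5.07 and -3.88 at the other probes of the last 2, and the claudin gene CLDN4 at -0.64. The call of CLDN4 was lost without the first or the second array of either group labelled BV173 (adjusted p from 0.0525 to 0.0736), with quantile normalization (0.076) and with normexp (0.14). The stromal list differed by a median of -8.08 between the same arrays as all of these groups.

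Genes of DNA replication and the G1/S transition were higher for 35 of 37 genes and lower for none on the arrays labelled BV173 in co-culture (median 0.75, adjusted p = 6.13e-09; adjusted p = 0.531 with an estimated correlation). GINS2, a subunit of the replicative helicase, differed by 1.29 (SE 0.12), RRM2, a ribonucleotide reductase subunit, by 1.25, CDC25A by 1.11 and CCNE2 by 1.09. Ribosome biogenesis and MYC-driven genes were higher for 22 of 28 genes and lower for none, and higher for 23 adjusted over the list alone (median 0.64, adjusted p = 1.2e-05; adjusted p = 0.597 with an estimated correlation). UTP20 differed by 1.38, ODC1, ornithine decarboxylase, by 1.11, PES1 by 1.11 and RRP12 by 0.97, while MYC itself differed by -0.0027 (SE 0.13, adjusted p = 0.988). MHC class II genes were higher for 7 of 12 and lower for none, and higher for 9 adjusted over the list alone (median 0.75, adjusted p = 0.0149; adjusted p = 0.508 with an estimated correlation). This call ended among genes well above background on all arrays (adjusted p = 0.213), in a range over the alternatives from 0.00025 to 0.508. Their transactivator CIITA differed by 2.75, with 1.104 at its other probe, followed by CD74 at 0.87, HLA-DMA at 0.86 and HLA-DRB1 at 0.83. B-cell precursor genes were higher for 12 of 22 and lower for 1 (median 0.62, adjusted p = 0.0445; adjusted p = 0.508 with an estimated correlation). RAG2 differed by 1.55 with 0.091 at its other probe, a call lost with the mean of the probes (adjusted p = 0.0977), CD79A by 1.43, and VPREB3 differed by -2.02. The call of the list was lost with quantile normalization (adjusted p = 0.229), among genes well above background on all arrays (0.35), with slide as a block (0.0637), without the first BV173 co-culture array (0.0769), without the second BV173 alone array (0.0568) and without the second HL-60 co-culture array (0.0512), and over all alternatives its adjusted p lay between 0.000149 and 0.508. Oxidative phosphorylation genes were higher for 12 of 38 genes and lower for 1, and higher for 11 adjusted over the list alone (median 0.27, adjusted p = 0.0232; adjusted p = 0.838 with an estimated correlation), and this call ended with quantile normalization (adjusted p = 0.99) and without the first BV173 co-culture array (adjusted p = 0.101), in a range over the alternatives from 0.000278 to 0.99. Its leading genes were NDUFS3 at 0.82, CYC1 at 0.70, ATP5F1C at 0.64 and CYCS at 0.61, with 1.04 at another of its probes. The stromal list differed by a median of -8.08 between the same arrays.

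Other marker lists did not pass for the arrays labelled BV173: endothelial genes (adjusted p = 0.843), T and NK cell genes (0.96), genes of mature myeloid cells (0.967), and erythroid genes (0.752). G2/M genes did not pass either (0.337), with 7 of 37 higher and 1 lower, and 4 higher adjusted over the list alone, nor did genes of apoptosis (0.521). The test pointed down for apoptosis and mature myeloid genes, whose medians were 0.090 and 0.27. Among the apoptosis genes TNFRSF10B, a death receptor, was at least 106-fold lower, BIRC3, an inhibitor of apoptosis, at least 26.5-fold lower, TNFRSF10A at least 2.89-fold lower, and BIK, a BCL2-family killer protein, differed by 2.85. CD274, which encodes PD-L1, differed by -2.62 (SE 0.72, adjusted p = 0.019) and CD44, a hyaluronan receptor, by -1.84. The call of CD274 was lost without the second BV173 alone array or the first or the second co-culture array (adjusted p from 0.0576 to 0.0674). CD47 (0.30, adjusted p = 0.062) and CXCR4 (0.29, adjusted p = 0.186) did not pass. BCL2, an inhibitor of apoptosis, differed by 0.94, with 0.53 at its other probe, and ABL1 by 0.80, while BCR (0.20, adjusted p = 0.156, with up to 1.06 at its other probes) did not pass. CDKN1A, the cell cycle inhibitor p21, differed by -2.37 (SE 0.20). Between the same arrays the stromal list differed by a median of -8.08, and whether stromal RNA brought these differences was not tested.

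The second comparison asks the same of HL-60. On the arrays labelled HL-60 in co-culture 548 of 23980 genes rose and 125 fell against those labelled alone, and 449 and 74 of these changed by at least 1 log2 unit. The falls numbered 192 with slide as a block and 312 with slide 1 only, where 61.6% of the calls were rises against 81.4%. They numbered 61 among genes well above background on all arrays, 46 in the authors' tables and 25 with the HL-60 arrays fitted on their own. Stromal genes rose here, in the opposite direction to the arrays labelled BV173: 25 of 36 rose and 3 fell over all genes, and 31 rose and 3 fell adjusted over the list alone. Their median log2 fold change was 2.84, or 2.08 with bounds (adjusted p = 1.57e-34; adjusted p = 0.253 with an estimated correlation), and it was 3.13 within slide 1, 2.84 within slide 2 and 2.84 with slide as a block. TGFBI rose by 8.52 (SE 0.31, n = 2 per group, limma adjusted p = 6.73e-06), from -4.70, well above background on 1 of the 2 arrays labelled alone, to 3.81. IGFBP7 rose at least 67.9-fold and CALD1, an actin-binding protein, at least 36.2-fold. The 3 that fell were THY1, by at least 35-fold, FSTL1, by a log2 fold change of -4.59, and DCN, by -3.32, above background on 1 of the 2 arrays labelled co-culture.

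Outside that list UCHL1 rose at least 151-fold, the collagenase gene MMP1 at least 131-fold, the smooth muscle actin ACTG2 at least 87.5-fold and TFPI2 at least 71.4-fold. Among genes well above background on all arrays of both groups, stromal list included, the largest rises were in COL1A1, a chain of type I collagen, by 5.20 (SE 0.54), and in the matrix gene SPON2, by 5.02. LOXL2, a collagen cross-linking enzyme, rose by 4.96, COL6A1 of the stromal list by 4.55, CXCL1 by 4.51, S100A6 by 4.44, the transporter gene ABCC3 by 3.74 and HMOX1 by 3.54. The call of CXCL1 rests on the brighter of its 2 probes: the other gave 0.71 and stood for the gene without any 1 array labelled BV173 alone or HL-60 in co-culture, where the call was lost (adjusted p from 0.722 to 0.901). Among the falls VGF, a secreted neuropeptide precursor, fell by 2.19, ANKRD55 fell by 2.08, and MPC2, a subunit of the mitochondrial pyruvate carrier, fell by 1.91. EN1 fell by 1.78, EPB42, a red cell membrane protein, fell by 1.75, ORM2 fell by 1.64 and FAM43A fell by 1.61. The call of ORM2 was lost without either HL-60 alone array, the second HL-60 co-culture array, the first BV173 alone array or the second BV173 co-culture array (adjusted p from 0.0738 to 0.207). PCBP4 was at least 6.79-fold lower, with a log2 fold change of -0.12 at its other probe, SLC22A13 at least 5.58-fold and NDN at least 4.45-fold. All 59 of the genes named by rule for this comparison that passed had the same sign within both slides, as did all 673 genes called. The calls rest on these same arrays, so this agreement is no separate support. With slide as a block 55 of the 59 passed, and the call of ORM2 ended (limma adjusted p = 0.0535).

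Of the 33 lists, 7 passed for the arrays labelled HL-60, 6 up and 1 down, camera with an estimated correlation called none, with 4 at an unadjusted p under 0.05, and fry called 5. The 7 became 13 without the second HL-60 alone array and 11 without the second co-culture array. Interferon-stimulated genes rose for 9 of 36 genes and fell for none, and rose for 11 adjusted over the list alone (median 0.11, adjusted p = 2.73e-05; adjusted p = 0.253 with an estimated correlation). The median was 0.10 within slide 1 and 0.31 within slide 2, and the adjusted p was 7.17e-05 with slide as a block. IFIT2, an RNA-binding antiviral protein, rose at least 2.07-fold from a level not well above background, IFIT1 at least 1.63-fold and IFIT5 at least 1.45-fold. XAF1 also passed, with both levels too near background for a fold. With normexp and quantile normalization the calls of IFIT2 (adjusted p = 0.0628), IFIT1 (0.144) and XAF1 (0.456) were lost. With the HL-60 arrays fitted on their own those of XAF1 (0.0845) and IFIT1 (0.117) were lost, and in the authors' tables that of IFIT1 (0.0668). The other probes of IFIT2 and XAF1 gave 1.70 and 0.50. Genes of MHC class I presentation rose for 4 of 17 genes and fell for none, and rose for 6 adjusted over the list alone (median 0.27, adjusted p = 3.11e-05; adjusted p = 0.253 with an estimated correlation). Their medians within the slides were 0.34 and 0.18, and the adjusted p was 0.000162 with slide as a block. HLA-C rose by 2.64 (SE 0.17) and HLA-B by 2.19 (SE 0.19). The other calls, of ERAP2 at 0.88 and PSMB8 at least 1.12-fold, were lost without either HL-60 co-culture array, the first HL-60 alone array, and most BV173 arrays (adjusted p from 0.0553 to 0.218), and with slide as a block (adjusted p of 0.0563 and 0.0553). The levels of HLA-C and HLA-B were 1.46 and 1.86 on the arrays labelled HL-60 in co-culture, where the stromal list rose by a median of 2.84. They were 8.04 and 8.42 on the arrays labelled BV173 alone, where stromal genes were high, and 8.05 and 8.35 on those labelled BV173 in co-culture, where stromal genes were low. High levels in both BV173 groups cannot show whether stromal RNA brought the rise on the arrays labelled HL-60, which was not tested.

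TGF-beta and BMP targets rose for 7 of 20 genes and fell for 1, and fell for 2 adjusted over the list alone (median 0.42, adjusted p = 2.73e-05; adjusted p = 0.253 with an estimated correlation). The medians were 0.52 and 0.56 within the slides, and the adjusted p was 8.44e-05 with slide as a block. CCN2, a matricellular protein, rose at least 3.02-fold, a call lost with normexp (adjusted p = 0.145). The feedback genes SKIL and SMAD7 rose by 2.25 (SE 0.15) and 1.93 (SE 0.19). NF-kB targets and cytokines rose for 6 of 28 genes and fell for none (median 0.32, adjusted p = 3.11e-05; adjusted p = 0.745 with an estimated correlation), with medians of 0.30 and 0.18 within the slides and an adjusted p of 7.17e-05 with slide as a block. Among genes well above background on all arrays the call of this list ended (adjusted p = 0.412), in a range over the alternatives from 2.76e-07 to 0.745. IL1B, an inflammatory cytokine, rose at least 59.2-fold, CCL2 at least 12.2-fold and LIF at least 3.61-fold, with 0.67 at its other probe and its call lost with the HL-60 arrays fitted on their own (adjusted p = 0.066). Cholesterol synthesis genes moved down as a list (median -0.25, adjusted p = 0.00128; adjusted p = 0.793 with an estimated correlation), with -0.21 and -0.24 within the slides and an adjusted p of 0.00288 with slide as a block. Only SQLE, squalene epoxidase, passed in that list over all genes, against 2 genes lower adjusted over the list alone, and it fell by 0.62, a call lost without any 1 of the 4 HL-60 arrays, the first BV173 alone array or the second BV173 co-culture array (adjusted p from 0.0569 to 0.132). The cholesterol list lost its call with slide 1 only (adjusted p = 0.0508), without the second co-culture array (0.137) and without the second alone array (0.284), in a range over the alternatives from 1.91e-05 to 0.793. Lysosome and autophagy genes moved up as a list (median 0.16, adjusted p = 0.009; adjusted p = 0.793 with an estimated correlation), with 1 of 27 past the test, GAA, at 0.66. Its medians were 0.20 and 0.10 within the slides, and the adjusted p was 0.00882 with slide as a block. The call of GAA was lost without the first alone or the second co-culture array (adjusted p of 0.0907 and 0.119), and that of the list without the first co-culture or the first alone array (0.249 and 0.325), in a range over the alternatives from 0.000234 to 0.793. The stromal list rose by a median of 2.84 on the same arrays as all of these groups.

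Lists of the cell cycle did not pass for the arrays labelled HL-60: G1/S genes had a median of 0.066 (adjusted p = 0.183) and G2/M genes 0.11 (adjusted p = 0.0922), with no gene of either past the limma test, and 0 and 2 genes at an unadjusted p under 0.05. CDKN1A fell by at least 2.86-fold (adjusted p = 0.00308), a call lost with the HL-60 arrays fitted on their own (0.0966) and in the authors' tables (0.0561). The erythroid list did not pass (adjusted p = 0.285), with ALAS2, the erythroid haem synthesis enzyme, up by 1.86 and EPB42 down. Epithelial, endothelial, T and NK cell, mature myeloid and B-cell precursor lists did not pass either (adjusted p = 0.773, 0.835, 0.156, 0.6 and 0.335), and for epithelial genes the test pointed up with a median of -0.023. Leaving out the second HL-60 alone array raised the falls from 125 to 416 and lowered the share of rises from 81.4% to 54%, and leaving out the first co-culture array lowered the falls to 76. The 673 calls became 267 with the HL-60 arrays fitted on their own, 341 in the authors' tables and 225 among genes well above background on all arrays.

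**Figure D3:**
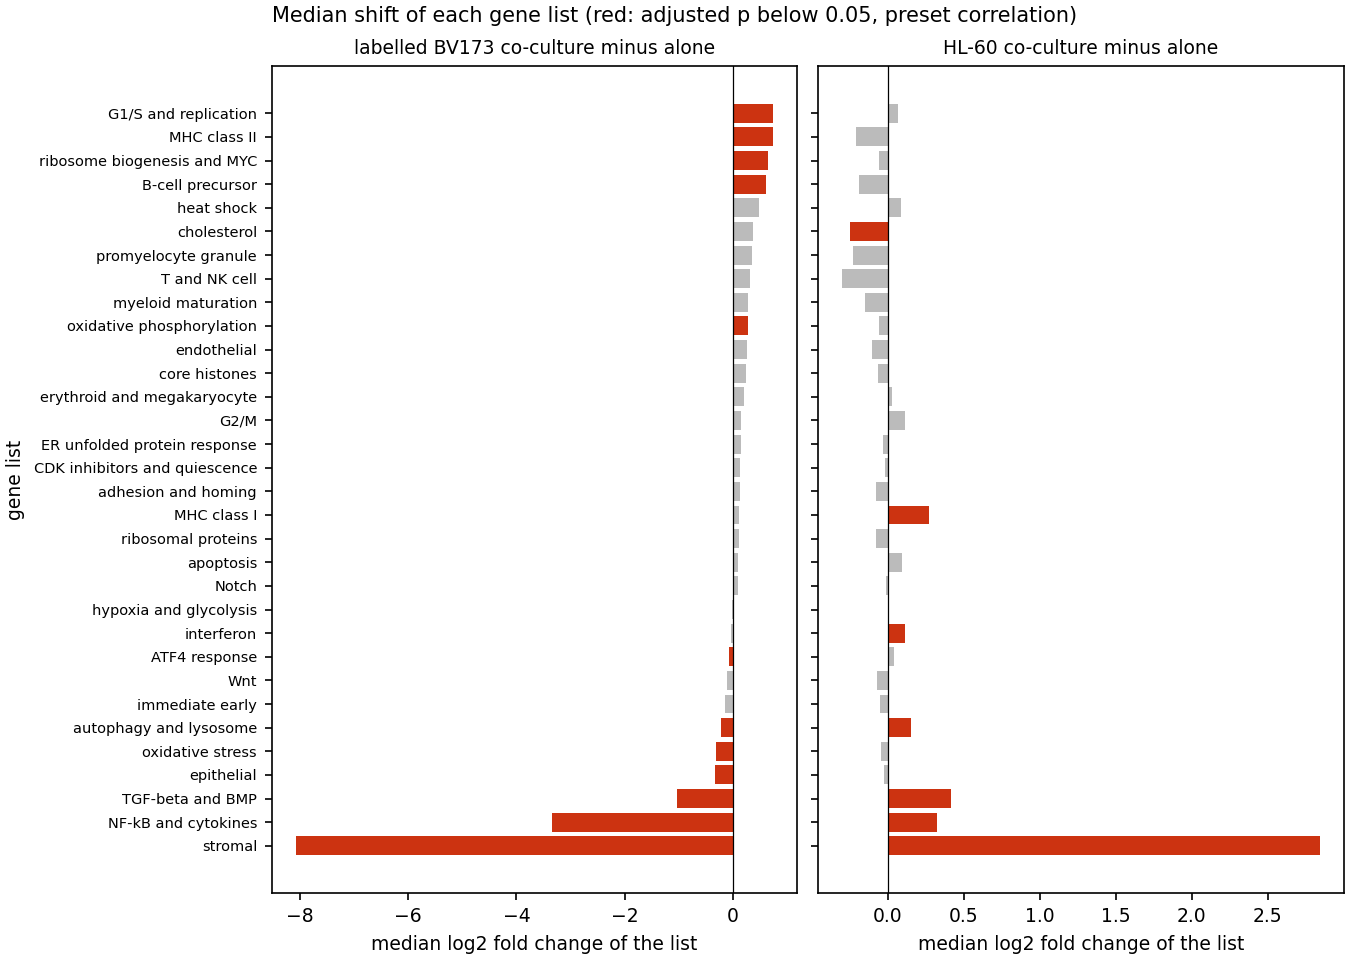
Median log2 fold change of each of 32 gene lists, co-culture minus alone as labelled, for BV173 (left) and HL-60 (right), on different horizontal scales. Red bars mark lists past the test at a preset correlation, 12 for BV173 and 7 for HL-60; the stromal list has medians of -8.08 and 2.84.

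The third comparison asks whether co-culture changed both lines alike. The 2 effects differed for 6669 genes, with the HL-60 effect the more positive for 3025 and the more negative for 3644. The latter count became 2386 without the second BV173 co-culture array and 2294 or 2301 without an HL-60 co-culture array, and the share of the former was 45.4%. Over the alternatives that keep the BV173 sign this share ran from 31.1% among genes well above background on all arrays to 64.8% with the percentile over probes above background on all arrays. With the sign of the BV173 comparison turned, as an alternative chosen after the conflict was seen, 5550 genes differed and the share was 55.8%. With the sign as labelled, COL6A1 differed most among genes well above background on all arrays, by 15.01 (SE 0.35, adjusted p = 8.94e-08), from -10.46 with BV173 and 4.55 with HL-60. In the opposite direction SCIMP differed by -4.82, from 4.52 and -0.30, and KCNMB3 by -4.10, from 3.66 and -0.44. These directions and their order rest on the BV173 sign. With it turned COL6A1 differed by -5.91 (adjusted p = 1.04e-05), SCIMP by 4.23 and KCNMB3 by 3.22, and the largest among these genes were then in FSTL1, by -13.63 (SE 0.50), and in KRT19, by -7.49.

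Of 461 genes that passed in both lines, 368 moved in opposite directions and 93 in the same direction, and turning the BV173 sign exchanges these counts. The 93 became 52 without the second BV173 co-culture array and 55 or 59 without the first or the third BV173 alone array. They became 20 with separate fits per line, 26 in the authors' tables, 43 among genes well above background on all arrays and 47 with no filter on dim probes, and stricter thresholds gave 35 at an adjusted p below 0.01 and 27 with at least 2-fold. Genes lower on the arrays labelled BV173 in co-culture and higher on those labelled HL-60 in co-culture numbered 320, against 82.6 for independent lists (Fisher's exact test, odds ratio 8.58, adjusted p = 3e-123). Those higher in both numbered 73 against 144 (adjusted p = 2.96e-13). The pair lower in both gave 20 genes against 18.8 (adjusted p = 0.802), and the pair higher with BV173 and lower with HL-60 gave 48 against 32.8 (adjusted p = 0.00392). Fisher's test counts genes as independent units, which they are not. These p-values therefore overstate the evidence and do not measure the spread between arrays. Across genes the fold changes had a Pearson correlation of -0.40 and a Spearman correlation of -0.17. The Pearson correlation was -0.189 among genes well above background on all arrays and -0.291 with no filter on dim probes. The largest opposite changes were in UCHL1, TGFBI, TFPI2, MMP1 and GREM1. The largest changes of the same sign were falls of THY1, FSTL1, NDN and DCN and of DKK1, a Wnt antagonist, which was at least 4.44-fold lower on the arrays labelled HL-60 in co-culture.

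**Figure D4:**
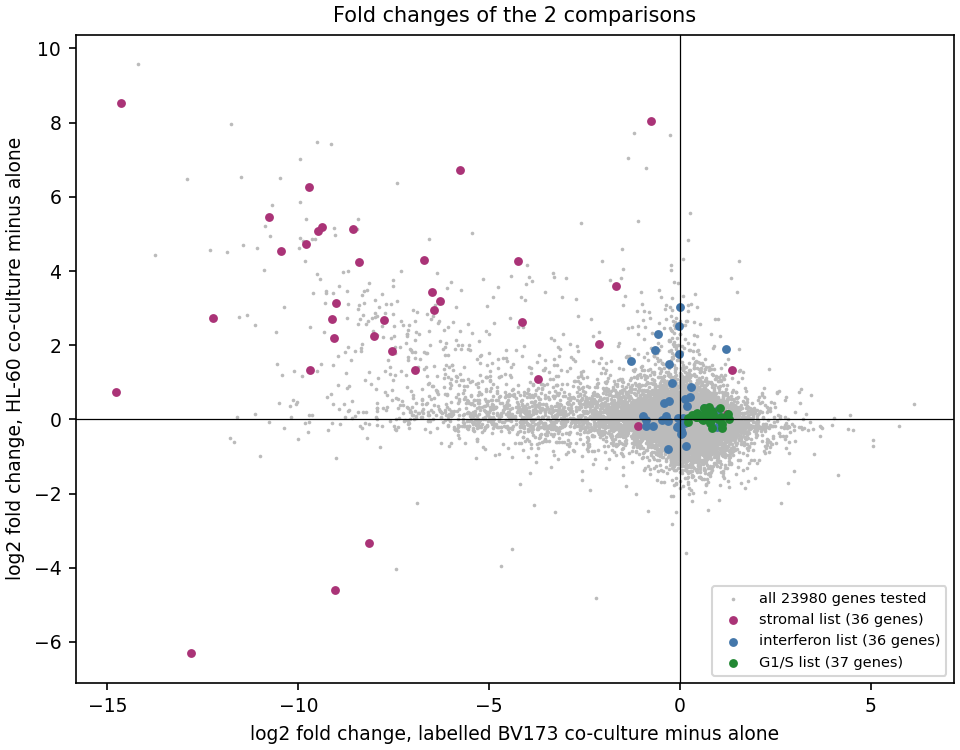
Log2 fold change of every gene tested, co-culture minus alone as labelled, with BV173 on the horizontal axis and HL-60 on the vertical axis. Each point is a gene, with the stromal, interferon and G1/S lists coloured; most stromal genes lie at the upper left, and THY1, FSTL1 and DCN at the lower left.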

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

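Of the tests in this part, those of stromal RNA, exchanged labels, scaling and slides were chosen only after the result was seen, and the count of other splits was chosen before. The turned sign of the BV173 comparison was also chosen after.

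The effects labelled co-culture minus alone differed between the lines for 6669 genes, by the test of the difference itself. In 10 genes named by rule the HL-60 effect minus the BV173 effect was 15.01 for COL6A1, 10.46 for SPON2, 9.65 for HMOX1, 9.48 for SPARC, a matrix protein, and 8.57 for CAVIN3, a component of caveolae. It was -4.82 for SCIMP, -4.10 for KCNMB3, -3.75 for BIK, -3.28 for CD84, a leukocyte surface receptor, and -3.21 for VGF. These sizes and their order rest on the BV173 sign. With it turned, 9 of the 10 genes changed sign, SPON2 did not pass (-0.42, adjusted p = 0.569), HMOX1 differed by -2.57, and 2 of the 10, SCIMP and KCNMB3, stayed among those the rule would name. The effects also differed for 15 gene lists at a preset correlation, of which 14 are described. The median of this difference was 10.35 for stromal genes, 4.10 for NF-kB targets, 1.98 for TGF-beta targets, 0.73 for oxidative stress genes, 0.60 for epithelial markers, 0.43 for interferon-stimulated genes, 0.37 for lysosome and autophagy genes, 0.23 for Wnt targets and 0.20 for ATF4 response genes. With each effect at its bound it was 8.29 for stromal genes, 2.59 for NF-kB targets and 1.66 for TGF-beta targets. The measured median was -0.97 for MHC class II genes, -0.72 for ribosome biogenesis genes, -0.64 for G1/S genes, -0.56 for cholesterol synthesis genes and -0.32 for oxidative phosphorylation genes. Camera with an estimated correlation called 0 of the 33 lists, with a smallest adjusted p of 0.191 and 5 at an unadjusted p under 0.05, and fry called 25. With the BV173 sign turned 7 lists passed, of which 6 are described, with medians of -4.29 for stromal genes (-4.01 with bounds), -2.23 for NF-kB targets (-1.56 with bounds), -0.61 for epithelial markers, 0.77 for G1/S genes, 0.64 for ribosome biogenesis genes and 0.43 for MHC class I genes. None of the 33 passed then with an estimated correlation (smallest adjusted p = 0.689), and 2 had an unadjusted p under 0.05.

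The stromal genes lay opposite to the labels of the BV173 arrays. Scaling alone is argued against, since the stromal median stayed at -5.66 or further from 0 under 3 other scalings. Exchanged labels of the 2 BV173 groups remain open. That 34 of 36 stromal genes lay higher on every array labelled alone than on every array labelled co-culture restates the pattern and decides nothing. Stromal RNA mixed with leukaemia RNA on the arrays labelled alone would follow from exchanged labels as well, so it is no rival to them. B-cell precursor genes lay lower there by a median of 0.62, against 0.19 over all genes tested, although VPREB3 went the other way (-2.02). The SE of 0.16 for this median is across the list's genes and not across arrays. The call of this list (camera adjusted p = 0.0445) was lost with an estimated correlation (0.508) and with quantile normalization (0.229), among other alternatives. Stromal cells in cultures rightly labelled alone cannot be told apart from exchanged labels, because all 36 stromal genes were well above background there while 19 were above it on no array labelled co-culture, and a change of the leukaemia cells themselves in co-culture stays open, untested.

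On the arrays labelled HL-60 in co-culture stromal genes rose, while THY1, FSTL1 and DCN fell. A constant difference between the slides is argued against by the design, since it cancels with 1 array of each HL-60 group on each slide. The stromal median was 2.84 or more within each slide. RNA from stromal cells may account for part of the rise, since 320 of the 548 genes that rose were also higher on the arrays labelled BV173 alone, against 82.6 for independent lists. Of the 548, 117 lay higher on the arrays labelled HL-60 in co-culture than on those labelled BV173 alone. THY1, FSTL1 and DCN were also higher on the arrays labelled BV173 alone, where THY1 lay at 6.04 and FSTL1 at 5.6. On the arrays labelled HL-60 in co-culture these 2 lay at -6.41 and -4.20, while TGFBI lay at 3.81. Added RNA like that on the arrays labelled BV173 alone would not lower them. Their falls argue against such RNA as the only change, for 3 of 36 stromal genes, against 25 that rose. No explanation of the fall of the 3 genes was tested. Induction of the genes that rose in the leukaemia cells by co-culture stays open, untested, and 155 of the 548 genes did not differ past the test between the BV173 groups.

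Of the 10 splits of the 6 BV173 arrays into 3 and 3, the labelled one called 9903 genes and the highest of the others called 0, and 1 of 10 is too few splits for a share under 0.05.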

How the results depend on the processing

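The normexp setting and the turned sign of the BV173 comparison were chosen after seeing the data, and the other alternatives before. The planned normexp on mean spot signal was not run, and it was run on the median spot signal. The authors' tables give no test of the difference between the lines and no label check. All 10 genes named for the difference kept sign and call under the alternatives that keep the BV173 sign. With it turned 9 reversed: COL6A1 to -5.91, SPON2 to -0.42, HMOX1 to -2.57, SPARC to -3.10, CAVIN3 to -3.56, SCIMP to 4.23, KCNMB3 to 3.22, BIK to 1.95 and CD84 to 2.22. Of 123 genes named for BV173, 116 kept their call whichever array was left out, and of 62 for HL-60, 49 did. With separate fits 23 of 62 HL-60 genes lost their call, among them FAM43A, CD24, MT1M, PCBP4 and TNFSF10 (adjusted p of 0.0557, 0.0557, 0.0591, 0.0764 and 0.114). With slide 1 only those of ABCC3, EPB42 and EN1 ended (0.064, 0.0902 and 0.1), among genes well above background on all arrays those of CXCL1 and PCBP4 (0.703 and 0.785), and with the mean of the probes that of BMF (0.0622). HL-60 ITGA6 reversed to -0.084 (adjusted p = 0.952) with the mean of its probes, as they go opposite ways.

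With an adjusted p below 0.01 the counts were 6504 genes and 7 lists for BV173, 367 genes for HL-60, 3492 for the difference and 208 of opposite sign in both lines. With at least 2-fold they were 3450 for BV173 and 4048 for the difference. These follow from stricter thresholds. With fewer genes tested, those well above background on all arrays, HL-60 had 225 genes, 99 were opposite and 9 of the B-cell precursor genes passed, against 21. Separate fits gave 267 HL-60 genes and 184 opposite, and the authors' tables gave 341 and 211. Separate fits have fewer arrays each. The authors' tables also differ in normalization and in the probes matched (21760 for HL-60), and the cause was not tested. Without a filter on dim probes 13 HL-60 lists passed, and the cause was not tested. With an estimated correlation 0 BV173 and 0 HL-60 lists passed, and fry called 22 for BV173. With the BV173 sign turned, 93 genes were opposite, by construction. The stricter filter also ended the calls of the NF-kB list for HL-60 (adjusted p = 0.412) and of MHC class II (0.213) and B-cell precursors (0.35) for BV173. The oxidative phosphorylation call also ended with the percentile over probes above background (0.203), the stricter filter (0.114), normexp (0.944) and the authors' tables (0.0605).

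Leaving out each array in turn gave 7938 to 10288 BV173 genes, 515 to 904 HL-60 genes, 4889 to 6855 for the difference, 249 to 404 of opposite sign, 12 to 14 BV173 lists, 6 to 13 HL-60 lists and 21 to 22 B-cell precursor genes. A lone array left in an HL-60 group was assumed to vary like the other groups. Signal near background limits fold changes, and 19 stromal genes have only bounds for BV173.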

Other observations

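The tests of the erythroid pattern and the choice of the pregnancy-specific glycoprotein (PSG) genes were made only after the result was seen.

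The PSG genes, a family of near-identical paralogs known from placenta, were higher on the arrays labelled BV173 in co-culture for 6 of 6 genes, with log2 fold changes from 2.15 to 3.99. On the arrays labelled HL-60 none of them passed, and 5 were above background on no array labelled HL-60. Probes of near-identical paralogs do not give independent values. Wnt targets did not pass for BV173 (adjusted p = 0.0513), with 7 of 18 lower and 5 higher. CCR7, a lymphoid homing receptor, differed by -4.25 on the arrays labelled BV173 in co-culture, in a list of adhesion and homing genes with 7 of 22 higher and 8 lower, a median of 0.14 and a test pointing down (adjusted p = 0.247). CCND1, the D-type cyclin, was at least 144-fold lower there. Between the same arrays the stromal list differed by a median of -8.08, and whether stromal RNA brought these differences was not tested.

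On the arrays labelled HL-60 in co-culture BMF, a BCL2-family killer protein, rose by 1.72, with 0.34 at its other probe, and the death ligand gene TNFSF10 rose by 1.54. MT1M, a metallothionein, rose by 3.11. CD24, a surface sialoglycoprotein, rose by 1.21. With the HL-60 arrays fitted on their own the calls of TNFSF10 (limma adjusted p = 0.114), MT1M (0.0591) and CD24 (0.0557) were lost. In the authors' tables that of TNFSF10 (0.0708) was lost. The stromal list rose by a median of 2.84 on the same arrays. THY1, FSTL1 and DKK1, which fell in co-culture, were above background on the arrays labelled HL-60 alone, where THY1 lay at -0.10 and FSTL1 at 0.39.

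Erythroid genes were high on the arrays labelled HL-60, and granule genes were not. That these arrays hold another line than the label is open, and which line they hold cannot be told from these data. The 11 of 13 erythroid genes higher there than on the arrays labelled BV173 alone restate the pattern and decide nothing. A minor share of erythroid cells among HL-60 cells would leave the granule genes high. On the arrays labelled HL-60 alone the granule median was -2.52, against 2.70 for erythroid genes. Well above background on all of these arrays were 9 of 10 granule genes and 12 of 13 erythroid genes. The medians argue against a minor share for the genes tested, although signals of different probes are not strictly on 1 scale. Of the granule genes, 2 were higher on the arrays labelled HL-60 and 4 on those labelled BV173. Levels set against those of BV173 do not give a share of cells, so this count cannot decide. EPCAM, an epithelial adhesion protein, lay at 4.65 on the arrays labelled HL-60 alone and was not well above background on those labelled BV173 alone. No biological explanation was tested, since the design gives none.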
